A study of Mus musculus with 23 samples.

How the data were processed

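Total RNA of the whole right lung of mice was labelled with biotin and measured on 23 arrays, per the labels. The values used were those of the series' deposited value table, 45101 probe sets by 23 arrays, whose probe set and control names are those of an Affymetrix mouse expression array. The deposited values are taken here to be log2 signals. This scale was inferred from the values, which were continuous, never negative, spread from 1.79 to 13.82 and alike in distribution on every array. Array means lay between 5.05 and 5.08 and array medians between 4.56 and 4.64, so the arrays had been brought to a common scale before deposit. The summary of probes to probe sets, the normalization and any centring are not given in the sources used here. Scanner files were not used here. No 2 columns held identical values (0 pairs). All 23 columns were matched to a sample and a group by the sample titles, and the replicate numbers are those of the titles.

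Affymetrix control probe sets (64) were left out of all tests, leaving 45037. Gene symbols came from the platform annotation of the series: 34945 probe sets had 1 symbol, 932 had several and 9160 had none. No gene was named from a probe set with several symbols. Of the probe sets with 1 symbol, 34741 had a gene ID in the NCBI RefSeq gene table of GRCm38.p6, and 0 symbols needed an update. That table was used only for names and for the order of genes along a chromosome. There were 18193 genes with a probe set of 1 symbol.

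Means of the 8 groups of strain, sex and genotype were fitted together with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 15 residual and 5.81 prior degrees of freedom, and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. All groups entered 1 fit so that they share an estimate of the spread, since no group had more than 3 arrays and the smallest two-sided exact permutation p for 3 against 3 is 0.1. The CF effect of a strain is the mean of its effects in both sexes, a strain difference of the CF effect is the BALB effect minus the B6 effect, and a sex difference is the female effect minus the male effect. In all, 13 comparisons were fitted, 5 of them main ones: the CF effect in B6, the CF effect in BALB, their difference, BALB minus B6 controls, and female minus male controls. Changes are differences of log2 signal, with the standard error of the limma fit. Where a median over a gene list has a standard error, it is taken over the genes of the list. It treats genes that move together as independent and measures no spread between arrays.

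Written before the data were examined were the groups, these comparisons, the alternatives and 44 lists of genes (21 of pathways and functions, 23 of cell type or tissue markers). The lists with at least 4 measured members (43) were tested on 1 probe set per gene (the one with the highest mean) with limma's camera at a preset inter-gene correlation of 0.01. They were tested again with camera's estimated correlation and with fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes. List p-values were adjusted over the lists within each comparison. Counts of list members past the threshold are given over all genes and adjusted over the list alone. List scores per array are means over the members of the value minus the gene's median over all arrays.

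The genes named in the text were chosen by a rule fixed beforehand. In each main comparison they are the 8 largest rises and 8 largest falls among probe sets with 1 symbol that passed 0.05, had the same sign in both sexes (for the sex comparison in both strains) and had a mean in the higher group at or above the median of all probe sets, 4.59, with 1 probe set per gene by lowest p. Where fewer than 3 genes passed in a direction, the 5 with the lowest p were to be named as not passing. Up to 4 members of lowest p were named from each list described. Cftr and the sex-linked label genes were always named, and for the sex differences and the effects within 1 strain and sex the 3 genes of lowest p in each direction. Values per array of Met, Tspan12, Krt4 and Acta1 were picked after they were seen.

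The model was tested on simulated data with the same groups and 45037 probe sets, some of which were given known changes. Of simulated changes of 0.5 (log2) the fit recovered 84.2% for the CF effect in B6, 91.4% in BALB, 46.7% for the strain difference, 92.3% for the strains and 87.5% for the sexes. At 1 it recovered 96.2% for the strain difference and 100% for the other comparisons. The share of calls on unchanged probe sets was 3.02% to 6.51%. With the T cell list shifted by 0.3, the list test gave it an adjusted p of 5.42e-18, and 1 unshifted list of the 43 passed. The simulated noise was independent between genes and between arrays. These simulations therefore cannot show how the list test or the share of false calls behaves where genes move together.

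Alternatives were quantile normalization, centring each array on its median, leaving out probe sets below the median level, eBayes with trend and robust settings, array weights, only the arrays of a comparison, 1 probe set per gene, the replicate number as a block, and leaving out each array in turn. After the data were examined, 2 alternatives were added: an intestinal score and a squamous and skeletal muscle score of each array as covariates, and leaving out B6 control female 1 and B6 control male 3 together. Counts of calls were also taken over up to 100 splits of the same arrays with labels dealt out again, drawn with seed 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.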

Results

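Gene expression in the whole right lung was compared between CF mice (CF-/-) and control mice (CF+/+) of the inbred strains C57BL/6 (B6) and BALB/c (BALB), in males and females. The labels name strain differences in cystic fibrosis as the subject of the series. Of the 23 arrays, each of the 8 combinations of strain, sex and genotype had 3, except CF males of B6, which had 2. The values were log2 signals of 45037 probe sets, and the number of arrays limited the precision of every comparison. Array medians lay between 4.56 and 4.64, and any 2 arrays correlated at 0.971 to 0.996 across probe sets. The largest axis of variation, with 33.7% of the variance, parted the strains. The labels do not say whether the arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Sex labels held on every array: Xist, the RNA that silences an X chromosome in females, read 8.79 to 10.13 on female arrays and 2.56 to 4.13 on male arrays by the probe set with the wider gap. The Y-linked Eif2s3y read 2.27 to 2.47 on female and 5.87 to 6.97 on male arrays.

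Cftr, the gene targeted in CF mice, which encodes the chloride and bicarbonate channel of epithelia, was measured in every sample first. In BALB it averaged 5.66 in controls and 3.99 in CF lungs, a fall by 1.67 (log2, SE 0.13, n = 6 and 6, adjusted p = 6.44e-07). No CF array (3.49 to 4.42) reached a control array (5.40 to 5.85). In B6 the control mean was only 4.28 and the CF mean 4.06, a difference of -0.22 (SE 0.13, n = 6 and 5, adjusted p = 0.43), with overlapping ranges of 4.04 to 4.58 and 3.86 to 4.31. The effect differed between strains by -1.45 (SE 0.18, adjusted p = 0.000258). The strains' CF lungs differed by -0.07 (SE 0.13, adjusted p = 0.794), and the controls by 1.38 (SE 0.13, adjusted p = 4.17e-08). By group, the brighter of the 2 Cftr probe sets, used throughout, read 5.70 ± 0.19 and 3.76 ± 0.32 in BALB control and CF females (SD, n = 3 each) and 5.62 ± 0.21 and 4.22 ± 0.31 in males (n = 3 each). In B6 it read 4.21 ± 0.16 and 4.05 ± 0.23 in females (n = 3 each), and 4.36 ± 0.22 (n = 3) and 4.07 ± 0.30 (n = 2) in males. Which part of the transcript the probe set covers, and whether the targeted allele removes it, was not analysed here. Cftr therefore checks the genotype labels in BALB and not in B6.

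Genes close to Cftr also differed between genotypes, and in B6 as well. Met, the hepatocyte growth factor receptor, fell by 0.75 in B6 (SE 0.09, adjusted p = 4.62e-05). It fell by 0.82 in BALB (SE 0.09, adjusted p = 3.82e-05). Tspan12, a tetraspanin of Norrin and Wnt signalling, fell by 0.34 (SE 0.05, adjusted p = 0.000383) and by 0.25 (SE 0.05, adjusted p = 0.00359). The ligand gene Wnt2 fell by 0.63 (adjusted p = 0.0172) and by 0.51 (adjusted p = 0.0388). These were the 3 genes past the threshold in both strains among the 80 measured neighbours, 40 on each side in the gene order of GRCm38.p6. Of these 80, 6 passed in B6 and 10 in BALB. Among all genes 6.09% and 5.9% passed. On each of the 5 B6 CF arrays Met read 7.18 to 7.65, against 7.91 to 8.18 on B6 control arrays, and Tspan12 read 5.54 to 5.83 against 5.96 to 6.14.

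**Figure D1:**
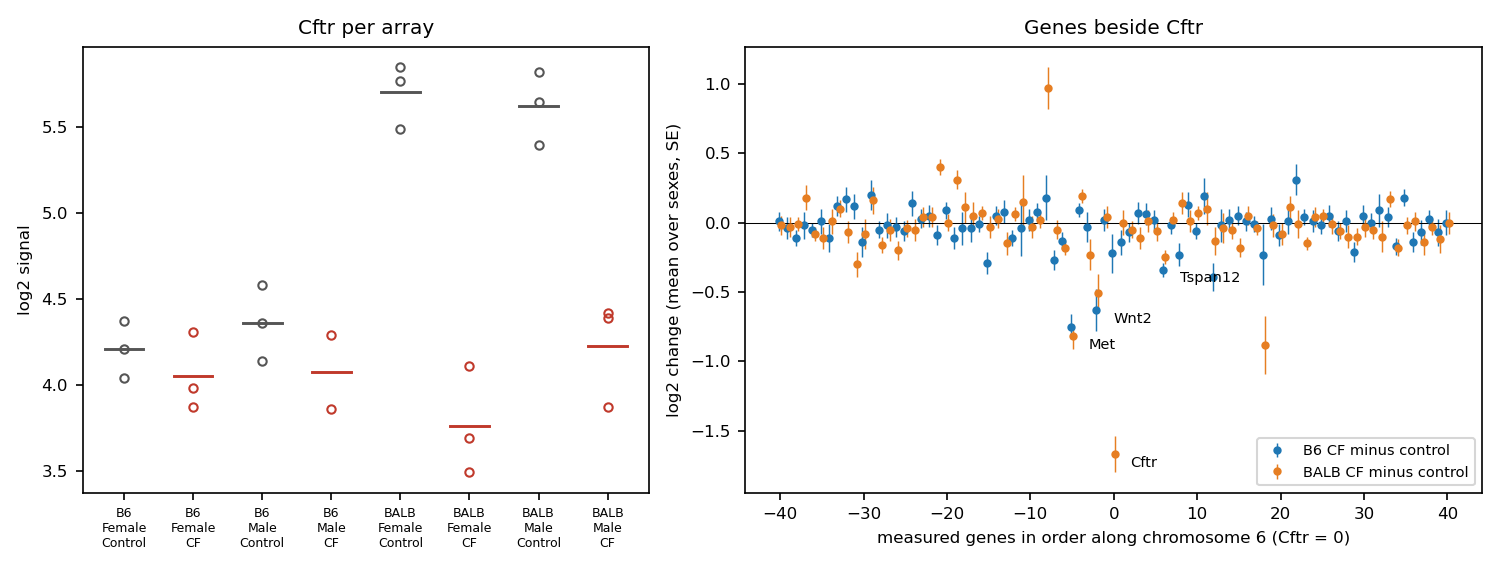
Left, log2 signal of Cftr on each array (circles) with group means (bars), controls in grey and CF in red: BALB controls sit at 5.40 to 5.85 and all other arrays at 3.49 to 4.58. Right, change from control to CF with its standard error for the 40 measured genes on each side of Cftr in gene order, B6 in blue and BALB in orange; Met lies at -0.75 and -0.82.

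In B6 lungs the CF mice had higher expression of T cell, natural killer cell, interferon and proliferation genes and lower expression of chaperone and cholesterol synthesis genes. Of these lists the proliferation list also held when the correlation between genes was estimated (adjusted p = 0.00592), and the others did not (adjusted p = 0.111 to 0.19 with an estimated correlation). The largest rises were those of Cxcl9, an interferon-gamma-induced T cell chemokine (2.47 on the log2 scale, SE 0.19, n = 5 and 6, adjusted p = 1.24e-06), and Ccl5, a chemokine made by activated T and natural killer cells (2.40, SE 0.24, adjusted p = 1.12e-05). Cxcl9 averaged 5.17 ± 0.83 in CF females and 3.60 ± 0.24 in control females (SD, n = 3 each), and 6.94 ± 0.09 (n = 2) and 3.57 ± 0.08 (n = 3) in males. The largest fall was that of Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, by 2.88 (SE 0.31, adjusted p = 1.93e-05).

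Of the 45037 probe sets, 2121 passed an adjusted p of 0.05 in B6, 1227 higher and 894 lower in CF. Of them 101 changed 2-fold or more, 93 upwards. Beside the chemokines, the named rises comprised the cytotoxic lymphocyte genes Nkg7 (1.86, SE 0.20, adjusted p = 1.92e-05), Klrg1 (1.64, SE 0.16, adjusted p = 1.12e-05) and Cd8b1 (1.65, SE 0.28, adjusted p = 0.00161). The immunoglobulin genes were Ighm (1.76, SE 0.39, adjusted p = 0.0117) and a kappa variable gene (2.02, SE 0.26, adjusted p = 9.6e-05). The interferon-induced GTPase Igtp rose by 1.67 (SE 0.41, adjusted p = 0.0214). The named falls included Cd209a, a lectin of dendritic cells (-1.22, SE 0.15, adjusted p = 6.74e-05), Lrat, which esterifies retinol (-1.02, SE 0.12, adjusted p = 3.49e-05), and Slc5a3, a myo-inositol transporter (-0.95, SE 0.13, adjusted p = 0.000156). The chaperones Hsph1 (-1.11, SE 0.25, adjusted p = 0.0111) and Hspa4l (-0.97, SE 0.17, adjusted p = 0.00151) fell with them. Nptx1 (-1.05) and Nrp1 (-0.97) fell by 1 probe set only, and by the brightest probe set of each gene they did not pass (-0.27, adjusted p = 0.0696, and -0.11, adjusted p = 0.406).

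Proliferation genes moved together in B6. Of the 35 members of the cell cycle list 24 rose (28 adjusted over the list alone), with a median of 0.44, among them Rrm2 (1.24, SE 0.13, adjusted p = 7.17e-06), Ccna2 (0.88, SE 0.09, adjusted p = 9.28e-06) and Tk1 (0.77, SE 0.08, adjusted p = 7.17e-06). The list's test gave an adjusted p of 6.13e-27, and an adjusted p = 0.00592 with an estimated correlation. Of 21 T cell markers 16 rose (19 adjusted over the list alone), including the receptor subunits Cd3g (1.45, SE 0.22, adjusted p = 0.000467) and Cd3e (0.72, SE 0.10, adjusted p = 0.000205) and the interleukin 7 receptor Il7r (0.83, SE 0.10, adjusted p = 6.32e-05), for a list adjusted p = 1.23e-21 and adjusted p = 0.111 with an estimated correlation. Natural killer cell markers rose in 8 of 17 (12 adjusted over the list alone), with granzyme B, Gzmb, at 1.30 (SE 0.20, adjusted p = 0.000431). For the natural killer list the test gave adjusted p = 9.3e-11, and adjusted p = 0.111 with an estimated correlation. Antigen presentation genes rose in 13 of 19 (16 adjusted over the list alone), among them Tap1, the peptide transporter (1.29, SE 0.22, adjusted p = 0.00122), and Psmb9 of the immunoproteasome (0.96, SE 0.16, adjusted p = 0.00104), with a list adjusted p = 1.52e-14 and adjusted p = 0.111 with an estimated correlation. Of 30 interferon response genes 12 rose (19 adjusted over the list alone), with Zbp1 at 1.43 (SE 0.26, adjusted p = 0.00233) and Oasl2 at 0.82 (SE 0.14, adjusted p = 0.00107). That list had adjusted p = 2.62e-11, and adjusted p = 0.174 with an estimated correlation.

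Among innate genes in B6, 7 of 20 neutrophil markers rose (9 adjusted over the list alone), with the receptors Cxcr2 (0.62, SE 0.10, adjusted p = 0.000652) and Csf3r (0.98, SE 0.17, adjusted p = 0.00141), for a list adjusted p = 1.38e-07 and adjusted p = 0.135 with an estimated correlation. Of 37 cytokine and chemokine genes 10 rose and 1 fell (16 and 2 adjusted over the list alone), with Il1b at 1.41 (SE 0.15, adjusted p = 1.41e-05) and Tnfaip3, an inhibitor of NF-kappaB, at 0.54 (SE 0.05, adjusted p = 4.98e-06). Its adjusted p was 1.38e-07, and adjusted p = 0.111 with an estimated correlation. Plasma cell markers rose in 4 of 9 (5 adjusted over the list alone), including Igha (1.18, SE 0.15, adjusted p = 4.57e-05) and Jchain (1.41, SE 0.20, adjusted p = 0.000162). The plasma cell list had adjusted p = 0.00507, and adjusted p = 0.19 with an estimated correlation. Immediate early genes rose in 7 of 25 (14 adjusted over the list alone), led by Nr4a1 (1.23, SE 0.23, adjusted p = 0.00234). Immediate early genes tested as a list had adjusted p = 1.38e-07, and adjusted p = 0.174 with an estimated correlation. The complement list passed at an adjusted p of 0.0191 (adjusted p = 0.446 with an estimated correlation), with the C1q genes C1qa, C1qb and C1qc at 0.79, 0.81 and 0.74; without control female 3 or CF male 2 its adjusted p was 0.0572 or 0.111.

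Chaperone genes went the other way in B6: of 28 members of the unfolded protein and heat shock list 15 fell and 1 rose (21 and 1 adjusted over the list alone), including Hsp90aa1 (-0.67, SE 0.11, adjusted p = 0.000926) and the mitochondrial Hspd1 (-0.62, SE 0.12, adjusted p = 0.00256). The list had a median of -0.40 and an adjusted p of 1.12e-15, and adjusted p = 0.135 with an estimated correlation. Cholesterol synthesis genes fell in 6 of 20 (9 adjusted over the list alone), among them Idi1 (-0.67, SE 0.12, adjusted p = 0.00164) and Hmgcs1 (-0.34, SE 0.08, adjusted p = 0.0129), with a list adjusted p = 1.38e-07 and adjusted p = 0.19 with an estimated correlation. Of the markers of the alveolar lining, 3 of 16 type 1 cell genes fell (7 adjusted over the list alone), with Igfbp2 at -0.68 (SE 0.12, adjusted p = 0.00187). For the type 1 cell list the test gave adjusted p = 5.87e-05, and adjusted p = 0.218 with an estimated correlation. Of 17 type 2 cell genes 3 fell and 1 rose (6 and 1 adjusted over the list alone), with the complement gene Hc at -0.71 (SE 0.06, adjusted p = 4.73e-06). The type 2 cell list had adjusted p = 0.000654, and adjusted p = 0.264 with an estimated correlation. The goblet, club and ciliated cell lists did not pass (adjusted p = 0.521, 0.463 and 0.153). Neither did ion and fluid transport of the airway epithelium (adjusted p = 0.463; median -0.02, mean 0.02). In that list 2 of 37 genes fell: the chloride channel Ano1 (-0.30, SE 0.07, adjusted p = 0.0125) and carbonic anhydrase Car2 (-0.24).

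With the preset correlation several of these B6 lists had a sex difference past the threshold, and with an estimated correlation those given here did not pass (adjusted p = 0.3 to 0.468). Interferon response genes rose in males in 18 of 30 (23 adjusted over the list alone; adjusted p = 2.2e-14, and adjusted p = 0.119 with an estimated correlation), and in females the list did not pass (median 0.06, adjusted p = 0.486). The sex difference of that list had adjusted p = 1.49e-10, and adjusted p = 0.3 with an estimated correlation. Immediate early genes rose in males in 11 of 25 (19 adjusted over the list alone; adjusted p = 2.5e-10, and adjusted p = 0.116 with an estimated correlation). In females their median was -0.04 and their mean -0.03 (adjusted p = 0.979, upwards by the test), and the sex difference had adjusted p = 3.48e-08, and adjusted p = 0.3 with an estimated correlation. The heat shock list did not pass in females (median -0.04, adjusted p = 0.725). Cholesterol synthesis and neutrophil lists did not pass in males (medians -0.03 and 0.22, adjusted p = 0.536 and 0.186). Their sex differences had adjusted p = 2.94e-06 and 0.0017, and adjusted p = 0.407 and 0.468 with an estimated correlation. Cell cycle genes rose in 16 of 35 in females and 13 of 35 in males (25 and 21 adjusted over the list alone), and a sex difference was not shown (adjusted p = 0.189).

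**Figure D2:**
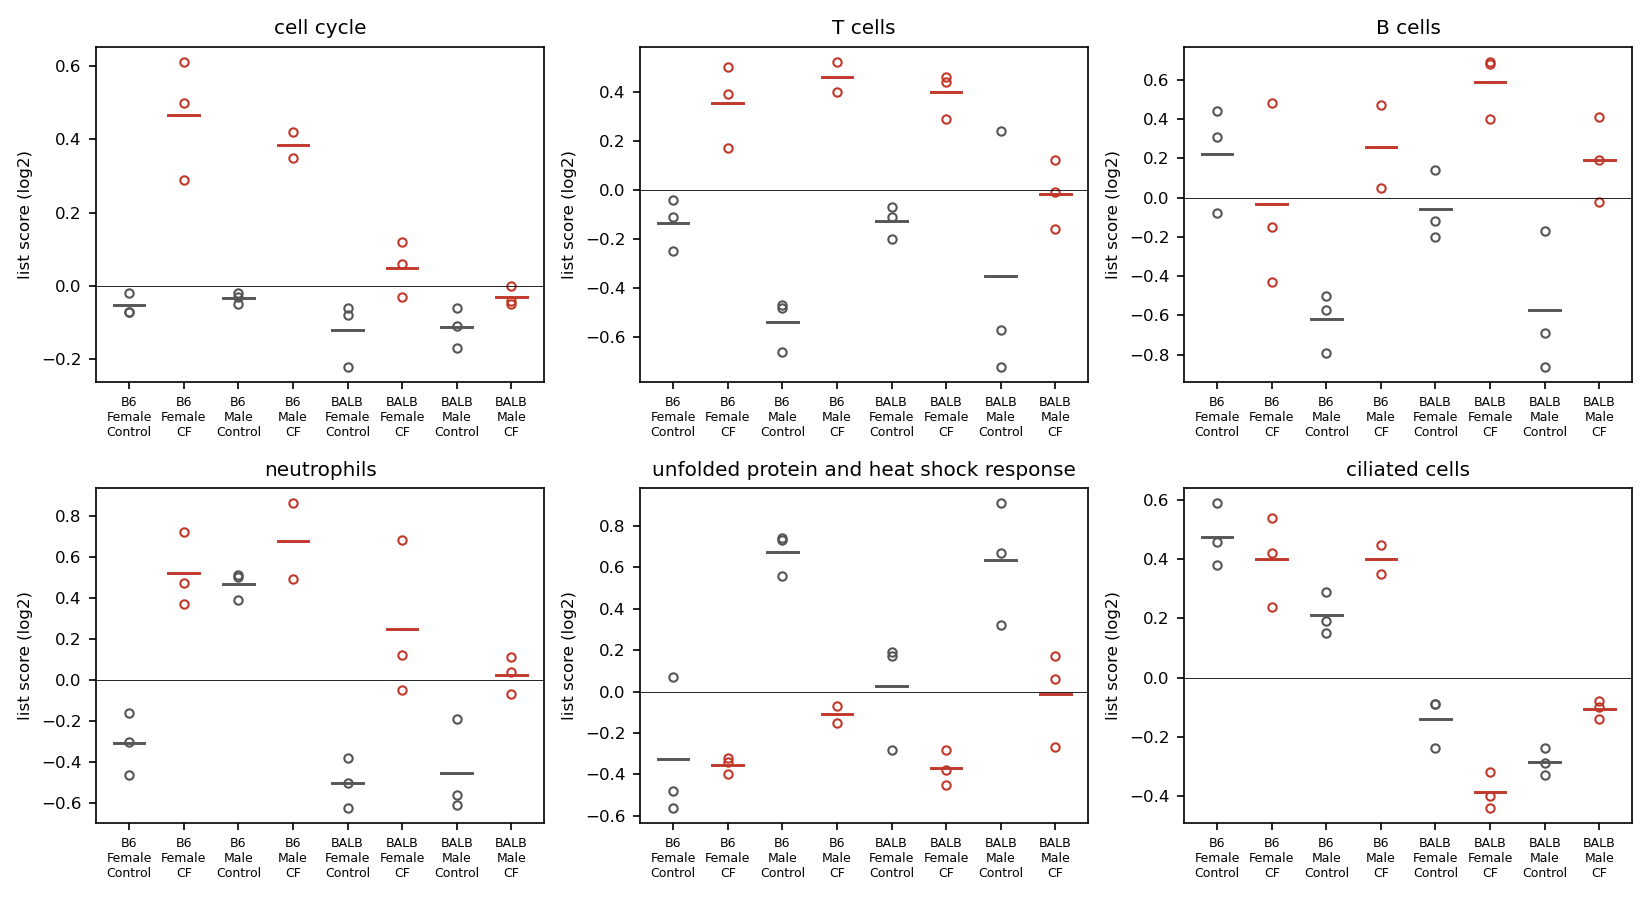
Mean log2 deviation of each array from the median array over the members of 6 gene lists (circles; bars are group means, controls in grey, CF in red). The cell cycle score averaged 0.47 and 0.38 in B6 CF females and males, against -0.05 and -0.03 in their controls, and 0.05 and -0.03 in BALB CF females and males, against -0.12 and -0.11 in theirs.

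The number of B6 calls leaned on particular arrays: it was 852 without CF male 1, 1329 without control female 3 and 1403 without CF female 3. Without CF male 1, Ighm (adjusted p = 0.136), Igtp (0.104) and Hsph1 (0.0892) no longer passed, and without CF female 3 Igtp did not (0.0593).

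In BALB lungs the CF mice had higher B cell, plasma cell, interferon and neutrophil genes and lower heat shock, glucocorticoid response and endothelial genes. Of these lists the plasma cell list also held when the correlation was estimated (adjusted p = 0.019), and the others did not (adjusted p = 0.124 to 0.335 with an estimated correlation). With scores for gut, squamous and muscle genes as covariates, added after the data were seen, the heat shock list was still lower in CF but did not pass (adjusted p = 0.164). The neutrophil calprotectin genes S100a9 and S100a8 rose by 1.77 (log2, SE 0.24, n = 6 and 6, adjusted p = 0.000158) and 1.76 (SE 0.25, adjusted p = 0.000279), and Slfn4, an interferon-induced myeloid gene, by 1.67 (SE 0.21, adjusted p = 9.58e-05). Cyp1a1 fell by 2.58 (SE 0.29, adjusted p = 3.73e-05), and its fall was not shown to differ from that in B6 (difference 0.30, SE 0.43, adjusted p = 0.818). The inducible heat shock genes Hspa1a (-3.27, SE 0.54, adjusted p = 0.00109) and Hspa1b (-3.26, SE 0.58, adjusted p = 0.00206) and the constitutive Hspa8 (-2.52, SE 0.30, adjusted p = 6.3e-05) fell as well. For Hspa1a the strain difference of the effect was -2.37 (SE 0.78, adjusted p = 0.118). Hspa1a averaged 6.49 and 10.37 in control females and males, and 4.17 and 6.16 in CF females and males (n = 3 each).

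In all, 2217 probe sets passed in BALB, 1169 higher and 1048 lower in CF, with 143 at 2-fold or more. B cell markers rose in 14 of 20 (17 adjusted over the list alone), among them Pou2af1 (1.22, SE 0.22, adjusted p = 0.00205), H2-Ob (1.16, SE 0.23, adjusted p = 0.00509) and Cd72 (0.76, SE 0.12, adjusted p = 0.000954), with a list adjusted p = 1.37e-16 and adjusted p = 0.157 with an estimated correlation. Plasma cell markers rose in 6 of 9 (6 adjusted over the list alone), with Jchain (1.21, SE 0.18, adjusted p = 0.000638), Igha (1.16, SE 0.14, adjusted p = 8.72e-05) and Mzb1 (0.84, SE 0.12, adjusted p = 0.000248); that list held at adjusted p = 6.33e-10, and adjusted p = 0.019 with an estimated correlation. Of 30 interferon response genes 15 rose (24 adjusted over the list alone), including Ifit3 (0.64, SE 0.07, adjusted p = 4.24e-05) and Rtp4 (0.72), with a list adjusted p = 2.57e-16 and adjusted p = 0.157 with an estimated correlation. In BALB females the interferon list did not pass (median 0.08, adjusted p = 0.138), and its sex difference had adjusted p = 1.29e-16, and adjusted p = 0.152 with an estimated correlation. Antigen presentation genes rose in 12 of 19 (15 adjusted over the list alone), with H2-DMb2 at 0.78 (SE 0.14, adjusted p = 0.00229). Antigen presentation genes tested as a list had adjusted p = 1.41e-13, and adjusted p = 0.157 with an estimated correlation. Of 21 T cell markers 7 rose (15 adjusted over the list alone), Il7r by 0.69 (SE 0.10, adjusted p = 0.000341). For the T cell list the test gave adjusted p = 8.38e-12, and adjusted p = 0.232 with an estimated correlation. Neutrophil markers rose in 9 of 20 (11 adjusted over the list alone), Csf3r by 0.98 (SE 0.16, adjusted p = 0.00111). The neutrophil list had adjusted p = 2.19e-11, and adjusted p = 0.124 with an estimated correlation. Among 37 cytokine and chemokine genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with the monocyte chemokine Ccl12 at 1.24 (SE 0.26, adjusted p = 0.00616) and Il1b at 0.70 (SE 0.14, adjusted p = 0.00612). Cytokine genes tested as a list had adjusted p = 1.5e-05, and adjusted p = 0.232 with an estimated correlation. Cell cycle genes rose in 4 of 35 (7 adjusted over the list alone), with a median of 0.10 (list adjusted p = 0.00014, and adjusted p = 0.335 with an estimated correlation). Natural killer cell markers rose in 3 of 17 (5 adjusted over the list alone), with a median of 0.17 (list adjusted p = 0.00133, and adjusted p = 0.405 with an estimated correlation). Neither list passed with the tissue scores as covariates (adjusted p = 0.134 and 0.277).

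Glucocorticoid response genes fell in BALB in 8 of 24, with 1 higher (14 and 1 adjusted over the list alone), led by Ddit4, an inhibitor of mTOR signalling (-1.43, SE 0.14, adjusted p = 1.11e-05), the clock gene Per1 (-1.35, SE 0.23, adjusted p = 0.00132) and the phosphatase Dusp1 (-0.98, SE 0.18, adjusted p = 0.00249). The list had adjusted p = 3.93e-10, and adjusted p = 0.232 with an estimated correlation. Of 25 immediate early genes 10 fell and 1 rose (11 and 2 adjusted over the list alone), with Klf2 (-0.87, SE 0.12, adjusted p = 0.000173) and Klf4 (-0.85, SE 0.13, adjusted p = 0.000489). For the immediate early list the test gave adjusted p = 0.000137, and adjusted p = 0.335 with an estimated correlation. In BALB males 10 of the 25 genes fell (17 lower and 2 higher adjusted over the list alone; adjusted p = 9.18e-10, and adjusted p = 0.202 with an estimated correlation). In females that list did not pass (median 0.04, mean 0.01, adjusted p = 0.739, downwards by the test), and the sex difference had adjusted p = 1.36e-06, and adjusted p = 0.275 with an estimated correlation. The heat shock list fell in 11 of 28 (13 adjusted over the list alone), Dnajb1 by 1.62 (SE 0.20, adjusted p = 9.79e-05). The heat shock list had adjusted p = 5.29e-08, and adjusted p = 0.335 with an estimated correlation. Endothelial markers fell in 6 of 19 (7 lower and 2 higher adjusted over the list alone), including Plvap of fenestrated endothelium (-0.56, SE 0.07, adjusted p = 0.000131). Endothelial genes tested as a list had adjusted p = 8.69e-05, and adjusted p = 0.335 with an estimated correlation. Of 37 ion and fluid transport genes 4 fell (2 higher and 8 lower adjusted over the list alone; adjusted p = 0.344), among them the calcium-activated chloride channel Ano1 (-0.22, SE 0.06, adjusted p = 0.0445) and Scnn1a, a subunit of the epithelial sodium channel (-0.30, SE 0.08, adjusted p = 0.0363). The goblet list did not pass (adjusted p = 0.538), with the intestinal score gene Tff3 at -1.98 (SE 0.48, adjusted p = 0.0169).

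Genes typical of gut and of squamous epithelium were among the largest BALB changes and varied between arrays of a group. Reg3b, an antibacterial lectin of the intestine, fell by 5.12 (SE 1.30, adjusted p = 0.0248), and the intestinal genes Zg16 (-2.86, SE 0.48, adjusted p = 0.00117), Fabp2 (-2.84, SE 0.51, adjusted p = 0.00206) and Fabp6 (-2.66, SE 0.46, adjusted p = 0.00158) fell too. The squamous keratins Krt4 (3.49, SE 0.97, adjusted p = 0.0405) and Krt13 (3.09, SE 0.87, adjusted p = 0.0427), with Serpinb12 (2.58), Sbsn (1.64) and Asprv1, were higher in CF. An intestinal score over 12 genes, chosen after the values were seen, read 0.47 to 2.91 on BALB control arrays, 1.98 on B6 control female 1, 1.18 on BALB CF female 1 and -0.20 to 0.00 on the others. A score over the squamous and skeletal muscle lists read 1.46, 1.81 and 3.04 on the BALB CF females, 2.77 on B6 control male 3, 0.86 on B6 control female 1 and -0.20 to 0.16 elsewhere. Krt4 read 9.94, 10.82 and 12.46 in those BALB CF females and 12.60 on that B6 control array, where the muscle actin Acta1 read 11.40. The same CF females had a lower 3' minus 5' difference of Gapdh (-0.20 ± 0.02, SD, n = 3) than the other groups (-0.09 to 0.03).

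With both scores as covariates, added after the data were seen, 31 BALB probe sets passed, 30 of them among the 2217. The factor by which the design scales standard errors grew 1.63-fold. A gene's own standard error also depends on its residual spread and fell for some genes, such as Krt4 (0.97 to 0.38). In that fit Reg3b was 0.55 (SE 1.01, adjusted p = 0.93), Krt4 1.29 (SE 0.38, adjusted p = 0.262) and S100a8 1.08 (SE 0.35, adjusted p = 0.317). Slfn4 (1.77, SE 0.33, adjusted p = 0.046) and Cyp1a1 (-3.30, SE 0.44, adjusted p = 0.0021) still passed. The heat shock (adjusted p = 0.164) and immediate early (adjusted p = 0.589) lists did not pass and kept their direction. Hspa8 was -2.51 (SE 0.48, adjusted p = 0.0532), where without the scores it was -2.52 (SE 0.30), so its call ended with the larger standard error. Hspa1a was -2.23 (SE 0.82, adjusted p = 0.411) and Hspa1b -2.27 (SE 0.87, adjusted p = 0.443), smaller falls with larger standard errors than without the scores (-3.27, SE 0.54, and -3.26, SE 0.58). The BALB count was 1368 without control female 1 and 1371 without control male 1. Without any 1 of 10 of the 12 arrays Krt4 lost its call (3.14 to 3.55), as did Krt13 for 11, Asprv1 for 11, Serpinb12 for 8, Sbsn for 8 and Reg3b for 6. CF female 3 was among them for each of these genes, and without it Krt4 had adjusted p = 0.0953, Krt13 0.104, Asprv1 0.116, Serpinb12 0.0862, Sbsn 0.0714 and Reg3b 0.065.

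**Figure D3:**
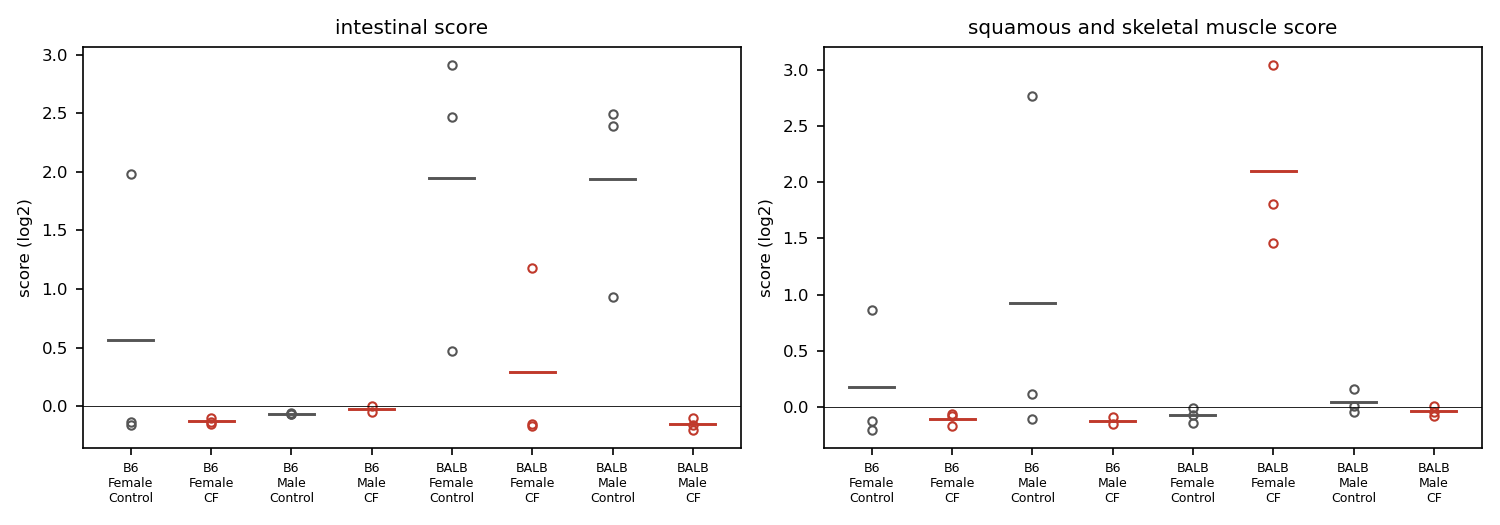
Intestinal score (left) and squamous and skeletal muscle score (right) of each array, as mean log2 deviation from the median array (circles; bars are group means, controls in grey, CF in red). The squamous and muscle score reached 3.04 in BALB CF females and 2.77 on B6 control male 3, and lay between -0.20 and 0.16 on most arrays.

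Taken over both strains, CF lungs had higher T cell, neutrophil, antigen presentation, cytokine, plasma cell and cell cycle genes. In this comparison 2878 probe sets passed, 1617 higher and 1261 lower. T cell markers rose in 18 of 21 (20 adjusted over the list alone), with a median of 0.50, and neutrophil markers in 12 of 20 (13 adjusted over the list alone), with a median of 0.42. Antigen presentation rose in 17 of 19 (19 adjusted over the list alone) and cell cycle in 23 of 35 (29 adjusted over the list alone). Plasma cell markers rose in 6 of 9 (7 adjusted over the list alone), and cytokines and chemokines rose in 14 of 37, with 1 lower (16 and 1 adjusted over the list alone). These 6 lists held with an estimated correlation: adjusted p = 0.0157 for cell cycle, 0.0246 for plasma cells and 0.045 for each of the other lists. Of all lists and comparisons, the others that held with it were cell cycle in B6, plasma cells in BALB, cell cycle and neutrophils in B6 females (adjusted p = 0.00132 and 0.0383), and interferon response and plasma cells in BALB males (adjusted p = 0.0447 and 0.00657). With the tissue scores as covariates 512 probe sets passed over both strains.

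The CF effect differed between the strains in the chemokine genes Cxcl9 and Ccl5, glucocorticoid response genes and cell cycle genes, among others. The list of cytokines and chemokines as a whole did not pass this test (median 0.02, mean -0.23, adjusted p = 0.242). The glucocorticoid and cell cycle lists each had adjusted p = 0.184 with an estimated correlation. Cxcl9 and Ccl5 each had an effect lower in BALB by 2.23 (log2, SE 0.27 and 0.33, n = 12 and 11, adjusted p = 0.000185 and 0.00117): in BALB they changed by 0.25 (adjusted p = 0.536) and 0.17 (adjusted p = 0.783). Glucocorticoid-induced genes rose in B6 in 5 of 24 (11 adjusted over the list alone), where the list had adjusted p = 3.71e-06, and adjusted p = 0.337 with an estimated correlation. In B6 females 4 of 24 rose (19 adjusted over the list alone; adjusted p = 4.22e-16, and adjusted p = 0.127 with an estimated correlation), where the control score was -0.36 ± 0.46 (SD, n = 3). In B6 males the list did not pass (median 0.14, mean 0.03, adjusted p = 0.726), and the sex difference had adjusted p = 2.2e-05, and adjusted p = 0.468 with an estimated correlation. Glucocorticoid response genes fell in BALB, and the strain difference of their effects had a median of -0.82. Of the 24 genes 9 had a lower effect in BALB (19 lower and 1 higher adjusted over the list alone), for a list adjusted p = 1.23e-15 and adjusted p = 0.184 with an estimated correlation. Examples were Ddit4 (-1.94, SE 0.20, adjusted p = 2.08e-05), Per1 (-2.04, SE 0.33, adjusted p = 0.00182) and Dusp1 (-1.65, SE 0.26, adjusted p = 0.00235).

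The direct test of the difference passed for 1142 probe sets, 602 with a higher and 540 with a lower effect in BALB. Of 25 immediate early genes 11 had a lower effect in BALB (17 lower and 2 higher adjusted over the list alone), including Nr4a1 (-2.15, SE 0.31, adjusted p = 0.00152) and Klf2 (-1.35, SE 0.17, adjusted p = 0.000325), with a list adjusted p = 6.43e-11 and adjusted p = 0.184 with an estimated correlation. Cell cycle genes had a lower effect in BALB in 9 of 35 (17 adjusted over the list alone), with Birc5 at -0.81, Mcm5 at -0.76 and Prc1 at -0.65 (SE 0.09, adjusted p = 0.00125). The cell cycle list had adjusted p = 4.74e-12, and adjusted p = 0.184 with an estimated correlation; its median was 0.44 in B6 and 0.10 in BALB. Of 17 natural killer cell markers 5 had a lower effect (6 lower and 1 higher adjusted over the list alone), Klrg1 at -1.64 (SE 0.23, adjusted p = 0.00109). Natural killer genes tested as a list had adjusted p = 0.00192, and adjusted p = 0.715 with an estimated correlation. Clock genes had a lower effect in 4 of 20 (10 lower and 3 higher adjusted over the list alone), with Hlf at -1.31 (SE 0.24, adjusted p = 0.00769). For the clock list the test gave adjusted p = 0.000431, and adjusted p = 0.575 with an estimated correlation. Single genes with a lower effect in BALB were Csrnp1 (-2.11, SE 0.21, adjusted p = 2.08e-05), Fam107a (-2.42, SE 0.44, adjusted p = 0.0044) and Cebpd (-1.84, SE 0.35, adjusted p = 0.00643). The interferon, antigen presentation and neutrophil lists did not pass this test (adjusted p = 0.428, 0.533 and 0.333; the interferon list had median 0.05 and mean -0.00).

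B cell markers had a higher effect in BALB as a list (median 0.37, 19 of 20 above 0; adjusted p = 4.23e-05, and adjusted p = 0.722 with an estimated correlation), with the lowest p for Fcer2a (0.85, SE 0.29, adjusted p = 0.132), which did not pass over all genes or adjusted over the list alone. The B cell call was lost with the tissue scores as covariates (adjusted p = 0.212). The plasma cell list had a higher effect as well (median 0.24, mean 0.08; adjusted p = 0.0242, and adjusted p = 0.575 with an estimated correlation), with 1 of 9 past the threshold (2 adjusted over the list alone), Prdm1 at 0.91 (SE 0.17, adjusted p = 0.00769). Its call was lost without B6 control male 1 (0.0549) or B6 CF male 2 (0.24). T cell markers had a lower effect in BALB as a list (median -0.29; 3 of 21 lower adjusted over the list alone; adjusted p = 0.00185, and adjusted p = 0.793 with an estimated correlation), lost without BALB control male 3 (0.0531).

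Among the named genes, the largest of the higher effects in BALB were those of squamous and muscle genes, namely Krt4 (5.87, SE 1.37, adjusted p = 0.0243), Krt13 (5.26, SE 1.27, adjusted p = 0.0289), Lor (4.88, SE 1.25, adjusted p = 0.04) and the fast troponin Tnnc2 (4.04, SE 1.07, adjusted p = 0.0467). These genes were high on the BALB CF female arrays and on B6 control male 3. Without B6 control male 3 the Krt4 difference was 4.59, and without B6 CF male 1 it was 5.90 with adjusted p = 0.0604. Krt13 did not pass without B6 CF male 1 (0.0724) or CF male 2 (0.0522), and Lor and Tnnc2 lost their calls without any 1 of 17 and 19 of the 23 arrays, at 4.41 to 5.08 and 3.55 to 4.29. Without both B6 control female 1 and B6 control male 3 the values were smaller and passed: Krt4 3.88 (adjusted p = 1.98e-05), Krt13 3.48 (0.000137), Lor 3.19 (0.000392) and Tnnc2 2.56 (0.0017). With the tissue scores as covariates they were 1.93 (0.0582), 1.50 (0.0353), 0.84 (0.369) and 0.71 (0.357). The count was 591 without B6 CF male 1, 748 without B6 control female 2 and 746 without B6 control female 3, and 203 with the tissue scores as covariates.

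Across probe sets the CF effects in the 2 strains correlated weakly (r = 0.15, rho = 0.08; probe sets are not independent replicates). Of the calls, 322 were higher in CF in both strains, where independent lists would share 31.8, and 80 were lower in both, against 20.8; 89 went opposite ways. The comparisons share no arrays. Of the B6 calls 66.5% had the same sign in BALB.

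**Figure D4:**
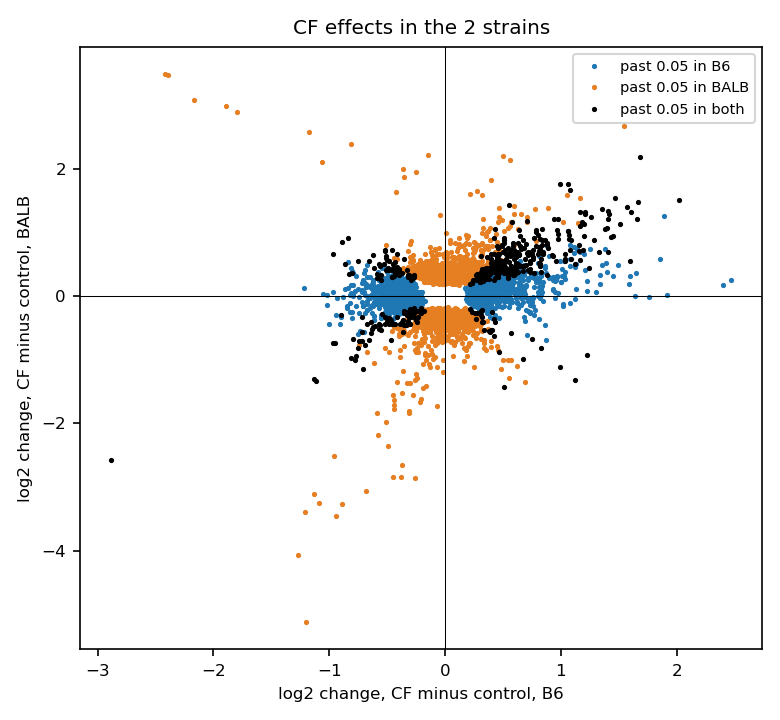
Log2 change from control to CF of each probe set in B6 (x axis) and BALB (y axis), coloured by whether it passed an adjusted p of 0.05 in B6, BALB or both. The effects correlated at r = 0.15; Cyp1a1 fell in both strains (-2.88 and -2.58), and Cxcl9 changed by 2.47 in B6 and 0.25 in BALB.

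Control lungs of the strains differed in ciliated, club and endothelial cell genes and in neutrophil and macrophage genes. With an estimated correlation these lists had adjusted p = 0.0885 to 0.967. Ciliated cell markers were lower in BALB in 29 of 33 (30 adjusted over the list alone), with a median of -0.57. They included Mlf1 (-1.13, SE 0.09, n = 6 and 6, adjusted p = 1.14e-08), Dynlrb2, a dynein light chain (-0.88, SE 0.07, adjusted p = 5.46e-09), and the radial spoke gene Rsph1 (-0.81, SE 0.06, adjusted p = 3.98e-09). The list had adjusted p = 1.79e-25, and adjusted p = 0.0885 with an estimated correlation. Club cell markers were lower in 8 of 14 (8 adjusted over the list alone), with the secretory gene Scgb3a2 at -0.54 (SE 0.05, adjusted p = 5.91e-08). The club cell list had adjusted p = 7.02e-05, and adjusted p = 0.372 with an estimated correlation. Endothelial markers were higher in BALB in 12 of 19, with 1 lower (14 and 2 adjusted over the list alone), including Gpihbp1, which anchors lipoprotein lipase (0.72, SE 0.06, adjusted p = 3.84e-08), and Car4 (0.54). Endothelial genes tested as a list had adjusted p = 2.51e-05, and adjusted p = 0.556 with an estimated correlation.

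Between control strains 7016 probe sets passed, 15.6% of those tested, 3361 higher and 3655 lower in BALB. Neutrophil markers were lower in 9 of 20 and higher in 1 (10 and 1 adjusted over the list alone), with the chitinase-like Chil3 at -2.12 (SE 0.18, adjusted p = 1.27e-08) and S100a8 at -1.33 (SE 0.25, adjusted p = 0.000536). For the neutrophil list the test gave adjusted p = 5.93e-05, and adjusted p = 0.556 with an estimated correlation. Alveolar macrophage markers were lower in 6 of 18 and higher in 1 (7 and 1 adjusted over the list alone), with Krt79 at -2.01 (SE 0.14, adjusted p = 6.52e-10) and the scavenger receptor Marco at -1.66 (SE 0.18, adjusted p = 8.79e-07). The macrophage list had adjusted p = 0.00554, and adjusted p = 0.967 with an estimated correlation. With the tissue scores as covariates that list had adjusted p = 0.0953. Of 17 type 2 cell genes 6 were lower (7 adjusted over the list alone). Type 2 cell genes tested as a list had adjusted p = 0.00362, and adjusted p = 0.714 with an estimated correlation. Plasma cell genes were higher in 4 of 9, Jchain by 1.84 (SE 0.18, adjusted p = 1.94e-07) and Igha by 1.68 (SE 0.14, adjusted p = 1e-08). The list's own call (adjusted p = 0.0452; 4 higher adjusted over the list alone; adjusted p = 0.714 with an estimated correlation) was lost without any 1 of 5 arrays: B6 control female 3 (0.0718), BALB control males 2 and 3 (0.0619 and 0.0532) and BALB control females 2 and 3 (0.0893 and 0.0686). In the goblet list 3 genes were higher and 3 lower, among the latter Bpifb1 (-2.20, SE 0.28, adjusted p = 6.67e-06) and the mucin Muc5b (-0.68, SE 0.16, adjusted p = 0.00357).

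The largest strain differences included H2-Ea, an MHC class II gene, with group means of 3.08 to 3.37 in B6 and 9.99 to 10.62 in BALB and a difference of 6.79 in controls (SE 0.10, adjusted p = 3.6e-21). The interferon-induced Gbp2b (4.46, SE 0.26, adjusted p = 3.4e-11), Serpina1b (4.01, SE 0.07, adjusted p = 1.78e-20) and Baiap2l1 (3.12, SE 0.06, adjusted p = 2.61e-19) were higher in BALB. Rpgrip1 (-4.50, SE 0.11, adjusted p = 2.7e-18), Ang (-4.44, SE 0.08, adjusted p = 1.78e-20), Sox11 (-4.43, SE 0.15, adjusted p = 1.42e-15) and Nxpe4 (-4.25, SE 0.09, adjusted p = 1.03e-18) were lower. Acoxl (-3.90) and Pttg1 (-3.25) were lower, and Reg3b of the intestinal genes was higher (4.98, SE 1.30, adjusted p = 0.00976; -0.13 with the tissue scores as covariates). Probe sets of a gene often disagreed here. Of 232 genes with several probe sets and a call of 2-fold or more, 33 had calls in both directions and 129 had a probe set without a call. H2-D1 (6.66), Pdxdc1 (4.29), Spon1 (3.72) and Rps9 (-3.83) changed sign with the brightest probe set of each (-0.04, -3.19, -0.24 and 0.14), and a probe set of Trim34a (-3.60) went the opposite way.

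Between control females and males the autosomal differences lay in heat shock, B cell and other immune, ciliated cell and cholesterol synthesis genes. With an estimated correlation the heat shock, B cell, ciliated cell and cholesterol synthesis lists had adjusted p = 0.147 to 0.254. Heat shock genes were lower in females in 18 of 28 (23 adjusted over the list alone), with a median of -0.47. Hspa1b differed by -3.84 (SE 0.61, n = 6 and 6, adjusted p = 0.00149), Hspa1a by -3.43 (SE 0.54, adjusted p = 0.0014) and Hsph1 by -2.18 (SE 0.23, adjusted p = 1.2e-05). Together the heat shock genes had adjusted p = 1.18e-29 and adjusted p = 0.147 with an estimated correlation. B cell markers were higher in females in 12 of 20 (18 adjusted over the list alone), including Ms4a1, which encodes CD20 (1.41, SE 0.29, adjusted p = 0.0107), and Pou2af1 (1.26, SE 0.21, adjusted p = 0.00248). For the B cell list the test gave adjusted p = 1.28e-13, and adjusted p = 0.217 with an estimated correlation. Further immune lists were higher in females: antigen presentation in 3 of 19 (13 adjusted over the list alone; adjusted p = 4.91e-08), natural killer cells in 3 of 17 (9; adjusted p = 4.35e-06), T cells in 5 of 21 (9; adjusted p = 2.52e-05), interferon response in 4 of 30 (7; adjusted p = 8.28e-05) and plasma cells in 4 of 9 (5; adjusted p = 8.28e-05). With an estimated correlation these 5 had adjusted p = 0.215 to 0.688. Ciliated cell markers were higher in 13 of 33 and lower in 1 (19 and 2 adjusted over the list alone), Tctex1d4 by 0.43 (SE 0.07, adjusted p = 0.00176). The ciliated cell list had adjusted p = 2.81e-10, and adjusted p = 0.254 with an estimated correlation.

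Past the threshold were 1094 probe sets, 729 higher and 365 lower in females, with Xist at 5.91 by the probe set with the wider gap and 3.55 by the one with the lowest p, and the Y-linked Eif2s3y, Kdm5d and Uty at -3.92, -2.75 and -1.78. Cholesterol synthesis genes were higher in females in 7 of 20 (13 adjusted over the list alone), with Hmgcs1 at 0.47 (SE 0.07, adjusted p = 0.00156). Cholesterol synthesis genes tested as a list had adjusted p = 4.48e-10, and adjusted p = 0.217 with an estimated correlation. Glucocorticoid response genes were lower in 4 of 24 (16 adjusted over the list alone), among them the cell cycle inhibitor Cdkn1a (-1.10, SE 0.22, adjusted p = 0.00653). For the glucocorticoid list the test gave adjusted p = 4.48e-10, and adjusted p = 0.254 with an estimated correlation. Neutrophil markers were lower in 6 of 20 (10 adjusted over the list alone), with Camp at -1.48 and the granule gene Ngp at -1.77 (SE 0.40, adjusted p = 0.0205). The neutrophil list had adjusted p = 3.79e-07, and adjusted p = 0.217 with an estimated correlation. The erythroid (adjusted p = 0.00338), skeletal muscle (0.00284), squamous (0.0144) and immediate early (0.0144) lists were lower too, with adjusted p = 0.447 to 0.714 with an estimated correlation. The skeletal muscle call was lost without B6 control male 3 (0.525), as was the squamous call (0.552), which was also lost without B6 control female 3 (0.0541) or BALB control male 3 (0.0529). The immediate early call was lost without B6 control female 2 (0.191) or BALB control male 2 (0.329). Clock genes went both ways, with 5 higher and 2 lower of 20 (8 and 4 adjusted over the list alone; adjusted p = 0.241): Dbp was higher by 1.78 (SE 0.25, adjusted p = 0.000443) and Nfil3 lower (-0.96, SE 0.13, adjusted p = 0.000254). The cold-inducible Cirbp (1.25, SE 0.21, adjusted p = 0.00268), the immunoglobulin gene Ighv14-2 (1.30, SE 0.28, adjusted p = 0.0158) and Ms4a4b of T cells (1.23, SE 0.21, adjusted p = 0.00288) were higher. Leaving out 1 array moved the count to 477 (BALB control male 1), 492, 650 and 1772 (B6 control females 2, 3 and 1), 628, 660 and 688 (B6 control males 1, 2 and 3) or 652 (BALB control female 1). Ighv14-2 did not pass without B6 control female 2 (0.0568), B6 control female 3 (0.0503) or BALB control male 1 (0.0562), nor Ngp without B6 control male 1 (0.0615) or male 3 (0.0555) or BALB control male 3.

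Within B6 males, T cell and B cell markers rose and chaperone genes fell, and within B6 females cell cycle and neutrophil genes rose and cholesterol synthesis genes fell. In the males 16 of 21 T cell markers rose (18 adjusted over the list alone; adjusted p = 3.06e-16, and adjusted p = 0.116 with an estimated correlation). In B6 males 2809 probe sets passed (1628 higher, 1181 lower; n = 2 and 3), with the antiproliferative gene Btg1 at 2.71 (SE 0.22, adjusted p = 8.89e-07), the histone gene H3f3b at 2.79 (SE 0.22, adjusted p = 8.89e-07) and Cxcl9 at 3.37 (SE 0.29, adjusted p = 2.13e-06). Of 28 heat shock genes 20 fell and 1 rose in these males (21 and 1 adjusted over the list alone), and 11 of 20 B cell markers rose (13 adjusted over the list alone). Heat shock genes tested as a list had adjusted p = 2.65e-20, and adjusted p = 0.106 with an estimated correlation. For the B cell list the test gave adjusted p = 3.07e-09, and adjusted p = 0.284 with an estimated correlation. In B6 females 367 passed (183 higher, 184 lower; n = 3 and 3), with Ccna2 at 1.01 (SE 0.12, adjusted p = 0.000733) and Ube2c at 1.23 (SE 0.17, adjusted p = 0.00134). Cxcl14 (-1.01, SE 0.12, adjusted p = 0.00067) and Lrat (-1.21, SE 0.16, adjusted p = 0.00118) fell. Cell cycle genes rose in 16 of 35 (25 adjusted over the list alone; adjusted p = 5.08e-36), neutrophil markers rose in 5 of 20 (12 adjusted over the list alone; adjusted p = 1.72e-15), and cholesterol synthesis genes fell in 6 of 20 (15 adjusted over the list alone). The cholesterol synthesis list had adjusted p = 1.62e-18, and adjusted p = 0.0502 with an estimated correlation. B cell markers were lower in these females as a list (median -0.17, adjusted p = 0.00547, and adjusted p = 0.772 with an estimated correlation).

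The direct test of a sex difference in B6 passed for 788 probe sets (307 with a higher and 481 with a lower effect in females), a count that 6 of 100 splits of the arrays reached. Btg1 (-2.75, SE 0.29, adjusted p = 0.000225), Plac8 (-2.22, SE 0.24, adjusted p = 0.000225) and Treml4 (-2.52, SE 0.29, adjusted p = 0.000263) had the lower effect in females. Zkscan3 (1.36, SE 0.18, adjusted p = 0.00106), the receptor gene Egfr (1.50, SE 0.21, adjusted p = 0.0019) and thrombomodulin, Thbd (0.82, SE 0.12, adjusted p = 0.0019), had the higher. Of 28 heat shock genes 12 had a higher and 1 a lower effect in females (18 and 1 adjusted over the list alone), and of 20 B cell markers 6 had a lower effect (13 adjusted over the list alone). Heat shock genes tested as a list had adjusted p = 1.04e-16, and adjusted p = 0.3 with an estimated correlation. For the B cell list the test gave adjusted p = 1.6e-11, and adjusted p = 0.3 with an estimated correlation. Without 1 array the B6 sex difference had 245 calls (CF male 1), 297 (CF female 1), 301, 483 and 1183 (control females 2, 3 and 1) or 375, 408 and 381 (control males 1, 2 and 3). The male effect had 760 (CF male 1), 1685, 1681 and 1726 (control males 1, 2 and 3), and the female effect 747, 93 and 84 (control females 1, 2 and 3), 194 (CF female 1) and 107 (CF female 3).

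In BALB males 867 probe sets passed (568 higher, 299 lower; n = 3 and 3) and interferon genes rose in 19 of 30 (23 adjusted over the list alone; adjusted p = 3.43e-29), with Ifit3 at 1.03 (SE 0.10, adjusted p = 2.58e-05). The chemokine receptor Ccr2 rose by 2.24 (SE 0.22, adjusted p = 2.58e-05). Plasma cell markers rose in 5 of 9 (6 adjusted over the list alone; adjusted p = 4.76e-12), and the co-chaperone Ahsa1 fell by 1.42 (SE 0.15, adjusted p = 4e-05). In BALB females 534 passed (260 higher, 274 lower; n = 3 and 3), with Ccr2 at 0.82 (SE 0.09, adjusted p = 0.000464), Ripor2 at 1.24 (SE 0.16, adjusted p = 0.00155) and Slamf6 of lymphocytes at 0.88 (SE 0.12, adjusted p = 0.0025). In these females, whose arrays carried the squamous and muscle signal, 9 of 15 skeletal muscle genes rose (14 adjusted over the list alone) and 4 of 33 ciliated cell markers fell (15 adjusted over the list alone). The skeletal muscle list had adjusted p = 7.86e-14, and adjusted p = 0.177 with an estimated correlation. Ciliated cell genes tested as a list had adjusted p = 2.07e-09, and adjusted p = 0.246 with an estimated correlation. The sex difference in BALB passed for 8 probe sets, a count that 5 of 100 splits of the arrays reached, with Phlda1 (1.19, SE 0.18, adjusted p = 0.0304) and Mid1 (1.17, SE 0.18, adjusted p = 0.0304) higher in effect in females. Spa17 (-1.15, SE 0.16, adjusted p = 0.0136), Mak (-1.09, SE 0.18, adjusted p = 0.0329) and Fam183b (-0.91, SE 0.15, adjusted p = 0.0399), all 3 known from cilia, had the lower effect. Without 1 array that count was 0 (limma) for control male 1, control female 1, CF female 3 or CF male 3, and with all arrays in 4324 probe sets had an unadjusted p under 0.05. It was 1 (control male 2 or CF female 2), 14 (control female 2), 2 (control female 3), 4 (CF male 2) or 100 (CF male 1). The male effect had 339 (control male 1), 426 (control male 2), 500 (CF male 2) and 323 (CF male 3), and the female effect 39, 1414 and 57 (control females 1, 2 and 3), 278 (CF female 1) and 53 (CF female 3).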

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

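The tests of a Cftr floor in B6 and of intestinal RNA on Cftr, and the 3 tests on gut, squamous and muscle genes, were chosen only after the result was seen; the test of mislabelled arrays and the counts over splits of the arrays were chosen before. All results here stand out because a direct test found that the CF effect differed between strains or between sexes. The strain difference passed for 1142 probe sets. In 100 splits of the arrays, drawn from 80000 possible ones, it reached 380 at most apart from the real labels (1 of 100 as large). These splits also broke the CF effect itself, so they cannot show whether that effect differs between the strains. Swapping CF and control labels on all BALB arrays would give the CF effect over both strains, with 2878 calls, and was not drawn. The sex difference in B6 passed for 788 probe sets, but 6 of 100 splits gave as many, up to 2121, so chance was not excluded. The split with 2121 swapped the labels of the females and thereby equals the B6 CF effect itself, a structure of the samples. The sex difference in BALB passed for 8 probe sets, and 5 of 100 splits gave as many, up to 466, so chance was not excluded there either.

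The Cftr effect differed between strains by -1.45, because Cftr fell in BALB and not past the threshold in B6. Mislabelled B6 arrays are argued against by Met and Tspan12, which on all 5 B6 CF arrays lay under every B6 control array of the same sex (values seen before), although for Wnt2 this held on 4 of 5 arrays, with overlapping ranges (5.08 to 6.22 against 5.96 to 7.06). The planned measure for this, the median B6 change over 6 neighbours changed in BALB (Met left out, Tspan12 included), turned by the BALB sign, was 0.18 and fell between its bounds, with 5 of 6 genes going the BALB way (one-sided exact sign test p = 0.109), or 0.13 and 4 of 5 without Tspan12. Intestinal RNA on the BALB control arrays is argued against as the whole cause, since the BALB change of Cftr was -1.69 with the tissue scores as covariates (SE 0.21, adjusted p = 0.00121). A candidate explanation is that Cftr signal in B6 controls was already near the floor of the probe set, their mean lying 0.29 above the BALB CF mean, while a strain variant under the probes or a lower transcript level in B6 was not tested.

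Among the named genes, squamous and muscle genes gave the largest strain differences: Krt4 5.87, Krt13 5.26, Lor 4.88, Krtdap 4.70, Rptn 4.04, Tnnc2 4.04, Serpinb12 3.75 and Ada 3.21, with the intestinal gene Zg16 at -2.60. Leaving out 1 array ended the call in 17 of 23 fits for Krtdap, 18 for Rptn, 19 for Serpinb12, 13 for Ada and 19 for Zg16, and by its brightest probe set Rptn was 0.23 (adjusted p = 0.337). A squamous change of the airway epithelium in CF is argued against, since skeletal muscle genes rose with the squamous ones in BALB CF females. The muscle median was 1.99 (SE over genes 0.48), with 15 of 15 genes higher. In BALB males the squamous test list had a median of -0.12. Oesophageal tissue on particular arrays may account for these genes. On B6 control male 3, 28 of 29 squamous genes not looked at before were higher than on its group mates. The median difference was 1.60 (SE over genes 0.33), and that of the skeletal muscle genes was 2.57 (SE over genes 0.60). However, 4 of these 29 squamous genes lay above the median level of all genes in B6 male CF lungs as well. For intestinal RNA the median over 29 other gut genes was 0.12 on B6 control female 1 (SE over genes 0.04, 24 of 29 higher). For the BALB change it was -0.08 (SE over genes 0.06, 24 of 29 lower, 4 past the threshold). The sizes set for it, 0.3 and -0.3, were not reached. The bounds against it were not passed, or by less than the standard error over genes. Without that margin, set after the value was seen, a passed bound counts against intestinal RNA. With it, intestinal RNA and a genotype effect cannot be told apart in BALB. Genotype alone does not account for differences within a group. The intestinal score, whose genes were chosen after the values were seen, was 1.98 on B6 control female 1 and -0.14 and -0.16 on its group mates. On BALB CF female 1 it was 1.18, against -0.15 and -0.17 on its group mates.

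Other genes whose CF effect was lower in BALB than in B6 were Fam107a (-2.42), Ccl5 (-2.23), Cxcl9 (-2.23), Csrnp1 (-2.11), Per1 (-2.04), Ddit4 (-1.94) and Cebpd (-1.84). In B6 the female effect was higher than the male effect for Zkscan3 (1.36), Egfr (1.50) and Thbd (0.82), and lower for Btg1 (-2.75), Plac8 (-2.22) and Treml4 (-2.52). In BALB it was higher for Phlda1 (1.19) and Mid1 (1.17), and lower for Spa17 (-1.15), Mak (-1.09) and Fam183b (-0.91).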

How the results depend on the processing

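The fits with tissue scores as covariates and without B6 control female 1 and B6 control male 3 together were chosen only after the result was seen. Quantile normalization and array weights kept sign and call of all 82 named genes, and leaving out dim probe sets of all 65 it could test; median centring and only the arrays of a comparison ended 1 call each, trend and robust settings 17, 1 probe set per gene 9 (4 more reversed), the tissue scores 24 (2 more reversed), leaving out B6 control female 1 and male 3 together 2 of 65, and leaving out 1 array at least once 20. Array weights raised the counts to 3824 in BALB, 2043 for the strain difference, 3666 for sex, 1488 for the sex difference in B6 and 132 for that in BALB. With 1 probe set per gene, fewer features, they were 1108 (B6), 1073 (BALB), 347 (strain difference), 1626 (both strains), 3536 (strains) and 447 (sex difference in B6), and H2-D1 (-0.04), Pdxdc1 (-3.19), Spon1 (-0.24) and Rps9 (0.14) reversed between strains, because the brightest probe set of each is another. With only a comparison's own arrays, fewer samples, they were 1406 (BALB), 24 (sex difference in BALB), 218 (B6 females), 210 (BALB females) and 387 (BALB males). Trend and robust settings gave 13 for the sex difference in BALB. With the tissue scores as covariates they were 31 (BALB), 203 (strain difference), 512 (both strains), 3277 (strains) and 0 (sex difference in BALB by limma, which had 4324 at an unadjusted p under 0.05 without the scores), the calls shared by both strains were 8 higher, 3 lower and 2 opposite, rho of the strain effects was -0.00, and Reg3b reversed in BALB (0.55) and between strains (-0.13). In that fit 99% of BALB calls kept their sign, with a median absolute change of 0.32 against 0.38. Without B6 control female 1 and male 3 B6 females had 648. Of 43 lists, 26, 21, 16, 8 and 15 passed in the 5 main comparisons (B6, BALB, strain difference, strains, sex); with an estimated correlation 1, 1, 0, 0 and 0 did, with fry 16 in B6, 13 in BALB, 3 for the strain difference and 9 for sex, and with all probe sets of the members 13 between strains. The cause of the changes was not tested except where fewer features or samples are named. Median centring moved the share of higher calls from 52.7% to 40.8% in BALB, from 52.7% to 37.8% for the strain difference and from 48.7% to 29.6% in BALB females.

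Leaving out 1 array gave 852 to 2329 calls in B6, 1368 to 2851 in BALB, 591 to 1568 for the strain difference, 477 to 1772 for sex, 245 to 1183 and 0 to 100 for the sex differences in B6 and BALB, 84 to 747 in B6 females, 760 to 2250 in B6 males, 39 to 1414 in BALB females and 323 to 975 in BALB males. A lone remaining B6 CF male array was assumed to vary like the other groups. Array numbers were not taken to pair the arrays, since over 77 same-numbered pairs deviations correlated at -0.18 to 0.35 (median -0.00, 15 above 0.1). As a hint from the data, 14 of 23 arrays matched best an array of their own number, against a mean of 7.7 with the numbers dealt out again (10000 draws, one-sided permutation p = 0.0312). With the number as a block the counts were 2081 (B6), 2173 (BALB), 1128 (strain difference), 2826 (both strains), 6919 and 8158 (strains in controls and CF), 1031 (sex), 771 and 8 (sex differences), 313 and 2672 (B6 females and males) and 554 and 876 (BALB females and males), and 1 named gene lost its call. The table was already on a log scale, so the alternative of log2 of the value plus 32 was not run. Signal over background was not given for these values, so dim probe sets were judged by their level alone.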

Other observations

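The test of lymph node or thymus tissue, the test of blood and the counts over splits were chosen before the result was seen; the test of natural killer against B cell markers by list means and within B6 females was chosen only after it. Between the strains in CF mice 8189 probe sets passed the threshold, 3902 higher and 4287 lower in BALB, and 6220 to 7943 did without 1 array (6220 without B6 CF male 1). Whether this count differs from the 7016 in control mice was not tested. Glucocorticoid response genes were lower in BALB CF lungs in 19 of 24 (20 adjusted over the list alone), with a median of -0.93 (adjusted p = 2.5e-09, and adjusted p = 0.338 with an estimated correlation), where in controls the list did not pass (median 0.03, adjusted p = 0.738). Natural killer cell markers were lower in 10 of 17 and higher in 1 (10 and 1 adjusted over the list alone), with a median of -0.93, adjusted p = 1.72e-05 and adjusted p = 0.354 with an estimated correlation. Cell cycle genes were lower in 23 of 35 and higher in 1 (25 and 1 adjusted over the list alone; adjusted p = 8.72e-10, and adjusted p = 0.124 with an estimated correlation). Plasma cell markers were higher in 7 of 9 (7 higher and 1 lower adjusted over the list alone; adjusted p = 3.11e-05, and adjusted p = 0.124 with an estimated correlation), and ciliated cell markers were lower in 30 of 33 (31 adjusted over the list alone; adjusted p = 1.59e-25, and adjusted p = 0.0878 with an estimated correlation).

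Clock genes differed between control strains in both directions, 9 of 20 higher and 5 lower in BALB, without a shift of the list (adjusted p = 0.166). Arntl, the activator of the clock, was lower (-1.46, SE 0.20, adjusted p = 1.45e-05), and Per3 (0.92) and Hlf (1.08), genes of the opposite arm, were higher. Times of sampling were not analysed here.

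Lymphocyte markers were higher in CF lungs of both strains, with T cell medians of 0.64 in B6 and 0.36 in BALB. But in B6 females B cell markers were lower (median -0.17, adjusted p = 0.00547) and T cell and natural killer medians were 0.45 and 0.23. None of these lists held there with an estimated correlation (B cells 0.772). More blood left in CF lungs is argued against as the whole cause, since erythroid markers had medians of 0.11 in B6 and -0.04 in BALB, under the 0.2 that was set. This does not hold within B6 females, where the erythroid score was 0.09 ± 0.09 in CF and -0.31 ± 0.32 in controls (SD, n = 3 each). In B6 males it was -0.13 in CF and -0.01 in controls. Lymph node or thymus tissue in the CF samples could not be excluded: by list medians natural killer markers exceeded B cell markers by 0.12 at most in either strain, and an excess over 0.3 had been set as the bound against it. By list means the excess was 0.40 in B6 (SE 0.18 over arrays) and -0.48 in BALB (SE 0.17), so in B6 it lay past that bound by less than its standard error. In B6 females it was 0.63 (SE 0.24), past the bound by more than that error, which speaks against lymph node tissue there; but their CF arrays differed, with B cell scores of -0.43, 0.48 and -0.15 against -0.08 to 0.44 in controls, and thymus tissue, which holds few B cells, is not addressed by this measure. The thymus list itself did not pass in B6 (adjusted p = 0.733, median -0.06, mean 0.14) or BALB (adjusted p = 0.944, median -0.02, mean 0.03). On BALB control male 3 the thymus score was 0.92, against -0.27 to 0.34 on all other arrays, which weighs on the BALB result. In BALB females it was 0.10 to 0.31 on CF arrays and -0.21 to -0.12 on control arrays. In BALB males it was -0.18 to -0.05 on CF arrays, and -0.21 and -0.27 on control males 1 and 2. Lymphocytes in the lung of CF mice may therefore be behind these genes, or lymphoid tissue taken with it, and these cannot be told apart here, since the planned measure fell short of its bound.

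Counts of calls were compared with 100 splits of the same arrays each. Only the real split of 100 gave as many for the CF effect in B6 (2121, highest other split 1442) and BALB (2217 and 271). The same held over both strains (2878 and 208) and for strains in controls (7016 and 2224) and CF mice (8189 and 5213). For sex in controls 2 of 100 gave as many (1094, highest other split 1151). With so few arrays chance is not excluded. Within 1 strain and sex 10 splits are too few for a share under 0.05: the real count and the highest other split were 367 and 0 in B6 females, 534 and 230 in BALB females and 867 and 10 in BALB males.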
